A study of Manduca sexta with 12 samples.

How the data were processed

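RNA from the antennae of adult male and female tobacco hornworm moths, Manduca sexta, and from larval midgut had been hybridised by the authors to one-colour Agilent arrays of 60-base probes, with cyanine 3 as the dye. There were 4 male antennal pools and 4 female antennal pools of 3 animals each, and 4 midgut pools of 5 larvae each, with 1 array per pool, so that a replicate is a pool and not an animal. Per the file headers, male pools 1 and 2 and female pools 1 and 2 shared slide 1, male pools 3 and 4 and female pools 3 and 4 shared slide 2, and the 4 midgut pools shared slide 3. On both antennal slides the male pools held places 1 and 2 and the female pools places 3 and 4. Replicate numbers paired no samples.

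The deposited scanner files give the signal of each spot as an intensity in arbitrary units, after the background subtraction and spatial detrending of Agilent Feature Extraction (version 9.1 per the labels, 9.1.1.1 per the file headers), with no normalization between arrays and with a surrogate value where a spot was not above background. The raw mean spot signal and the local background are deposited in the same unit, intensity. Other columns are deposited as flags of 0 or 1, among them whether a spot was well above background. The deposited value table holds log2 values, which the authors had quantile-normalized over the 12 arrays and centred on the median of each probe. The labels name the analysis software but no test.

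Control spots were left out and the 38107 remaining spots were averaged into 37117 probes, with spots marked as outliers treated as missing on their array. Signals were put on a log2 scale and the 75th percentile of each array was subtracted. The plan did not state the probes over which that percentile is taken. It was taken over the 8506 probes well above background on all 12 arrays, because a large share of all probes was undetected on each array, and the percentile over all probes was run as an alternative. Normalized signals are therefore log2 values relative to the 75th percentile of the commonly detected probes, and values below 0 are ordinary. The number of arrays limits the precision of every value, and intensities give no counting error.

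A probe was tested if it was well above background on all arrays of at least 1 of the groups compared. Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistic, two-sided), with the package data.table (version 1.17.8) for reading. Adjusted p-values were obtained by the method of Benjamini and Hochberg over all probes tested in a comparison, with a threshold of 0.05. Male and female antennae were compared on the 8 antennal arrays. Antenna, as the mean of the sexes, was compared with larval midgut on all 12 arrays. Group values are given as mean ± SD over arrays, and differences as log2 with the standard error of the fit. Where no array of the lower group was well above background, its value on each array was raised to the lowest signal called well above background on that array, and the ratio is given as at least that many fold. A fitted difference against a group that was undetected on some or all of its arrays is no measured fold. An adjusted p given beside such a limit belongs to the fitted difference, which uses the background values of undetected arrays, and not to the limit.

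These comparisons, tests, thresholds and most alternatives were chosen before the data were examined, as was the rule for the genes named. That rule takes, per comparison and direction, the 10 named genes with the largest difference among probes past the threshold whose groups do not overlap and which were well above background on all arrays (the first part), and the 5 brightest named genes past the threshold that were well above background on all arrays of the higher group and on none of the lower (the second part). A gene with several probes is given by the probe with the highest mean signal over the arrays compared. Probes without a describing name are limited to 2 per direction. Further parts of the rule, for 31 fixed gene lists and for named odorant receptors and binding proteins, could not be used. The array gives describing names only within a block of 130 probes. Of the 31 lists, 0 had members on the array, and 0 array names were found in the reference table of gene symbols. The tests of those lists and the planned comparison of Z-linked with autosomal genes were therefore not run.

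Most of the 130 probes of that block carry single words as names (olfactory, odorant, candidate, chemosensory, gustatory and others), which read as the first word of a longer description. Once these words had been read, olfactory, odorant, chemosensory, gustatory and melatonin were taken as describing names in the rule for named genes, while candidate, isoform and reverse, which describe no protein, were not. The block is called the receptor block here, since most of its probes carry words used for chemosensory receptor genes. Which protein each probe detects is not stated in the files. The block was read as 65 targets of 2 consecutive probes each, since both probes of all 65 pairs share a name. Of these pairs, 31 overlap by at least 20 bases, and 0 of the 64 pairs shifted by 1 probe do. Of the 65 pairs, 37 are named olfactory, 10 odorant, 10 candidate and 2 chemosensory, and 2 are named ---NA---. The pair CUST_121_PI424196207 and CUST_122_PI424196207 repeats the sequences of the pair before it, so at most 64 of the 65 targets are different. Most of the other probes carry contig names of a sequence assembly (32788 probes), GenBank accessions (3543 probes) or the name PROT_fasC with a number (458 probes). A small remainder carries names of other forms.

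After these names were seen, 13 groups with at least 5 targets were formed from them, 3 from words of the receptor block, 9 from the letters of the GenBank accessions and 1 from PROT_fasC. They were tested with camera of limma, a competitive test, with a preset correlation of 0.01, 1 probe per target and Benjamini-Hochberg adjustment over the groups, and again with the correlation estimated from the data. Letters of accessions mark batches of sequence submissions and not functions. Probes that share a stretch of 25 bases were joined into clusters (34836 in all), and counts of clusters are given beside counts of probes over the whole array, and for groups where they differ from the counts of targets.

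The fits were tested on simulated data, 10 sets of arrays per comparison with the measured means and spreads. For the sexes, a mean of 45.6% (38% to 51%) of probes changed by 1 on the log2 scale and 84% (79% to 88%) of those changed by 2 were recovered, with 80 false calls among 1376. For the tissues, 29.2% (18% to 38%) and 76.5% (73% to 83%) were recovered, with 62 false calls among 1119. A group of probes shifted by 0.5 was called in all 10 sets of both comparisons, and 0 other groups were. The simulated probes varied independently of each other and without a slide effect. The simulation therefore does not show how often groups are falsely called on the real arrays. There, wrong divisions of the antennal arrays reached up to 9 groups.

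The alternatives covered normexp background correction (offset 50), quantile normalization, scaling to the array median, no filter and a stricter filter on dim probes, eBayes with an intensity trend and robust priors, the authors' value table, leaving out each array in turn, slide as a block, each antennal slide alone, all 12 arrays in 1 fit, each sex alone against midgut, slide as a random block, a minimum of 2-fold, and 1 probe per target. Scaling to 3 bright spike-in probes, the percentile over all probes, 1 probe per cluster and a filter on the higher group were added after the data were examined, as were the counts and medians of the receptor block, the tests of the 13 groups and their alternative with repeated sequences counted once. The tests of single named probes followed the rule above, with describing names chosen once the words had been read.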

Results

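Gene expression was measured in male antenna, female antenna and larval midgut of Manduca sexta, with 4 arrays per group, each from a pool of 3 animals (antenna) or 5 larvae (midgut). The antenna is the main olfactory organ of the adult moth, and the midgut is the digestive tissue of the feeding larva. Between 10534 and 19565 of the 37117 probes (28.4% to 52.7%) were well above background on an array. The 75th percentile of the intensity of commonly detected probes lay between 9534 and 14934 on the antennal arrays and between 1595 and 3392 on the midgut arrays. On all 4 arrays of a group, 10158 probes (27.4%) were well above background in male antenna, 10791 (29.1%) in female antenna and 15249 (41.1%) in larval midgut. Of these, 9693 were detected on all arrays of both antennal groups, 521 on all 8 antennal arrays and no midgut array, and 3091 on all 4 midgut arrays and no antennal array. Of the 130 probes of the receptor block, 42 were well above background on all male arrays, 60 on all female arrays and 0 on all midgut arrays. Most of the 130 are named by words used for chemosensory receptors. Across detected probes, which are not independent replicates, the correlation between arrays was 0.9435 to 0.9776 among male pools, 0.9415 to 0.9878 among female pools, 0.9516 to 0.9757 among midgut pools and 0.6077 to 0.6775 between antenna and midgut. Between the sexes it was 0.9462 to 0.9743 on the same slide and 0.9168 to 0.9467 across slides, while pools of the same sex on different slides gave 0.9415 to 0.9590.

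The first comparison asked which transcripts differed between the antennae of the sexes. Olfactory receptors are the membrane proteins by which insect sensory neurons detect odours, and in moths the male antenna also senses the sex pheromone released by females. A pair of olfactory targets was detected on every male array and on no female array. All other receptor-block targets that passed the test had lower signals in the male. The 65 probes of the block that were tested stand for 39 targets (38 different ones, as 1 pair repeats another). Of them, 4 probes of 2 targets were higher in male antenna, 37 probes of 25 targets were higher in female antenna and 24 probes did not pass the test. Detection on all arrays of 1 sex sufficed for entry, which favours that sex, and 37 of the 65 were detected on all 8 antennal arrays. With detection required on all 8, 18 block probes were higher in female and 0 in male antenna, with a median log2 difference of -1.08. The median log2 difference between male and female of the 65 probes was -1.11, also with undetected groups at their limit, and -1.19 with the repeated sequence counted once, while the median of all probes tested was -0.09.

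The target with the largest male signal was represented by CUST_3_PI424196207 (olfactory, probe sequence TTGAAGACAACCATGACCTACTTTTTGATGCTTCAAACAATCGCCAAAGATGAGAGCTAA). Its normalised log2 signal was 2.62 ± 0.11 in male antenna (SD, n = 4), while it was not well above background on any of the 4 female arrays. It was at least 229-fold higher in the male (limma, adjusted p = 2.69e-05). Its partner probe, also not well above background on any female array, was at least 116.5-fold higher there. The other male target, CUST_82_PI424196207 (olfactory, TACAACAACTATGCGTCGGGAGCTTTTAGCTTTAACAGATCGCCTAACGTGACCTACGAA), had a signal of 1.30 ± 0.25 in male antenna (SD, n = 4) and was at least 91.9-fold higher there (limma, adjusted p = 4.60e-05), a limit for the background-subtracted signal, as the log2 difference was 6.06 with normexp background. No named gene fell under the first part of the rule in this direction, since none of those higher in the male was detected on all female arrays.

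In the other direction, CUST_2_PI424196207 (olfactory, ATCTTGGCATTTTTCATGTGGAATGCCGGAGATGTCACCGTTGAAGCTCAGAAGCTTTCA) had a signal of -0.59 ± 0.09 in female antenna (SD, n = 4) and was well above background on no male array. It was at least 26.5-fold higher in the female (limma, adjusted p = 0.00204), with the same direction in its partner probe. The same part of the rule named a further 4 targets, whose brightest probe was detected on all female and no male arrays. They were CUST_56_PI424196207 (olfactory), at least 6.31-fold higher, CUST_108_PI424196207 (odorant), at least 5.74-fold, CUST_77_PI424196207 (odorant), at least 3.20-fold, and CUST_94_PI424196207 (olfactory), at least 2.88-fold, with adjusted p between 0.000876 and 0.00782. The partners of CUST_56_PI424196207 and CUST_77_PI424196207 were each well above background on 2 of 4 female arrays and were not tested, so these 2 targets rest on 1 probe each. CUST_94_PI424196207 lost its call with normexp background (adjusted p = 0.0585), CUST_77_PI424196207 within slide 1 alone (0.240) and CUST_2_PI424196207 within slide 2 alone (0.0707). The limits hold for the background-subtracted signal, and with normexp background the log2 differences of CUST_2_PI424196207, CUST_56_PI424196207 and CUST_77_PI424196207, at -3.82, -1.79 and -1.25, were smaller than their limits. Outside the rule and chosen after its values were seen, CUST_103_PI424196207 (olfactory) was also detected on all female and no male arrays and was at least 11.7-fold higher in the female (limma, adjusted p = 0.00310), while its brighter partner CUST_104_PI424196207 was detected on 2 male arrays.

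Among targets detected on all 8 antennal arrays, the largest difference was that of CUST_21_PI424196207 (odorant, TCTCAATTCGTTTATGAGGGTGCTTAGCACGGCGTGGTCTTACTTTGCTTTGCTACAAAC). Its signal was -1.81 ± 0.18 in female and -3.93 ± 0.68 in male antenna (SD, n = 4 each), and it was 4.33-fold higher in the female (limma, adjusted p = 0.0101). CUST_46_PI424196207 (olfactory) had signals of 0.02 ± 0.15 in female and -1.57 ± 0.28 in male antenna, a log2 difference of -1.59 ± 0.17 (standard error, limma, adjusted p = 0.00227). The other 8 targets under this part of the rule had log2 differences of -1.44 for CUST_80_PI424196207, -1.37 for CUST_89_PI424196207, -1.34 for CUST_65_PI424196207, -1.27 for both CUST_5_PI424196207 and CUST_16_PI424196207, -1.11 for CUST_12_PI424196207, -1.06 for CUST_97_PI424196207 (all named olfactory) and -0.93 for CUST_84_PI424196207 (odorant). The partner probes of CUST_5_PI424196207 and CUST_12_PI424196207 had the same direction but did not pass the test (adjusted p = 0.0543 and 0.110). The partner of CUST_65_PI424196207 was too dim to be tested. CUST_84_PI424196207 was past the threshold under 6 of 23 alternatives and lost its call without any 1 of the 8 arrays, and CUST_16_PI424196207 was past it under 15 of 23 and lost its call without male pool 1 or 2 or female pool 1, 3 or 4. None of the 10 passed with spike-in scaling or within slide 1 alone, where each kept its direction. Without the filter on dim probes 8 of the 10 lost their call, and only CUST_46_PI424196207 and CUST_80_PI424196207 passed.

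By name, 27 of the 46 tested olfactory probes were higher in female antenna, 4 in male antenna, and 15 did not pass the test, with a median log2 difference of -1.19, or -1.15 with undetected groups at their limit. Of the 10 odorant probes, 8 were higher in female and 0 in male antenna, with a median of -1.78 (-1.72 with limits). Of the 7 candidate probes, 2 were higher in female and 0 in male antenna, with a median of -0.73. Of the 37 block probes detected on all 8 antennal arrays, 34 had a lower mean in the male. The probes that did not pass included both of an olfactory target with a higher mean in the male, CUST_92_PI424196207 and CUST_91_PI424196207, at 1.38 and 1.71 (adjusted p = 0.141 and 0.163). Both chemosensory probes that were tested, CUST_7_PI424196207 and CUST_8_PI424196207, had differences of 0.29 and 0.34 (limma, adjusted p = 0.355 and 0.408). These 4 probes were chosen after their values were seen.

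**Figure D1:**
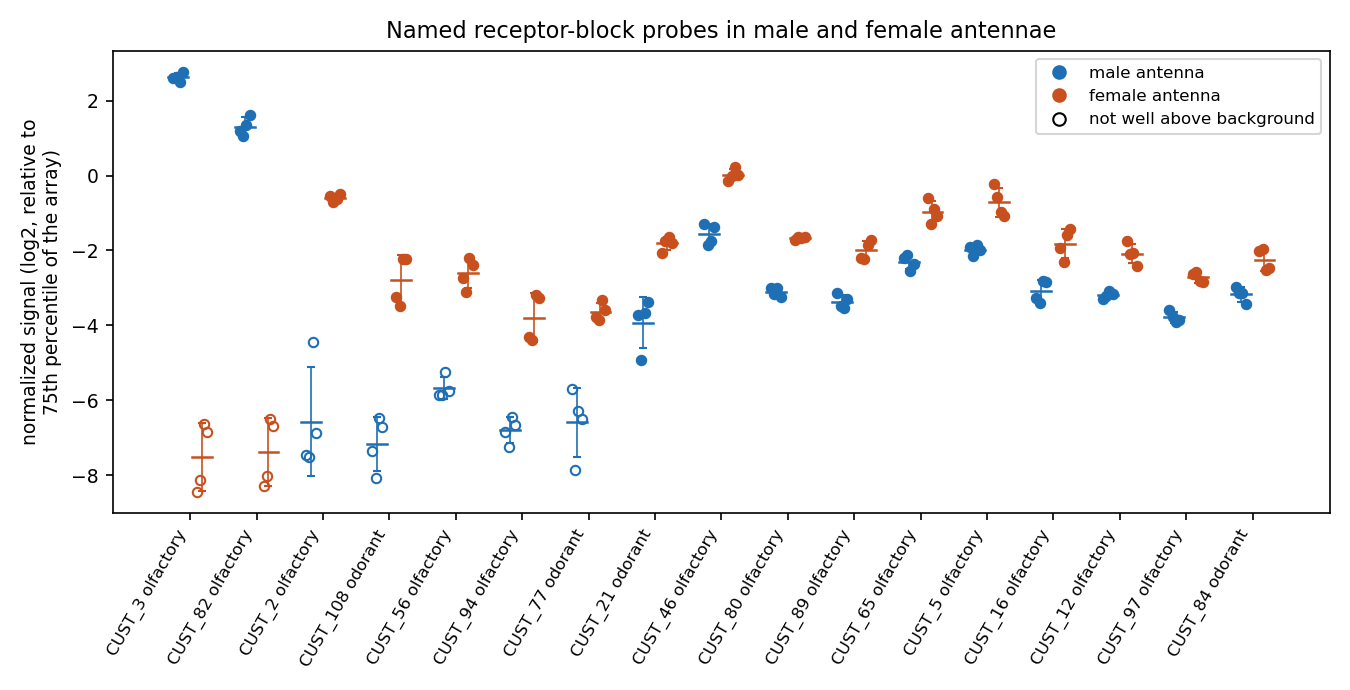
Normalised signal (log2, relative to the 75th percentile of the array) of the 17 receptor-block probes named for the sex comparison in male (blue) and female (orange) antenna, with 1 point per array, a bar at the mean, SD as error bars (n = 4) and open points for arrays not well above background. CUST_3 and CUST_82 had means of 2.62 and 1.30 in male antenna and only open points in female antenna, while the other 15 were lower in male antenna.

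**Figure D2:**
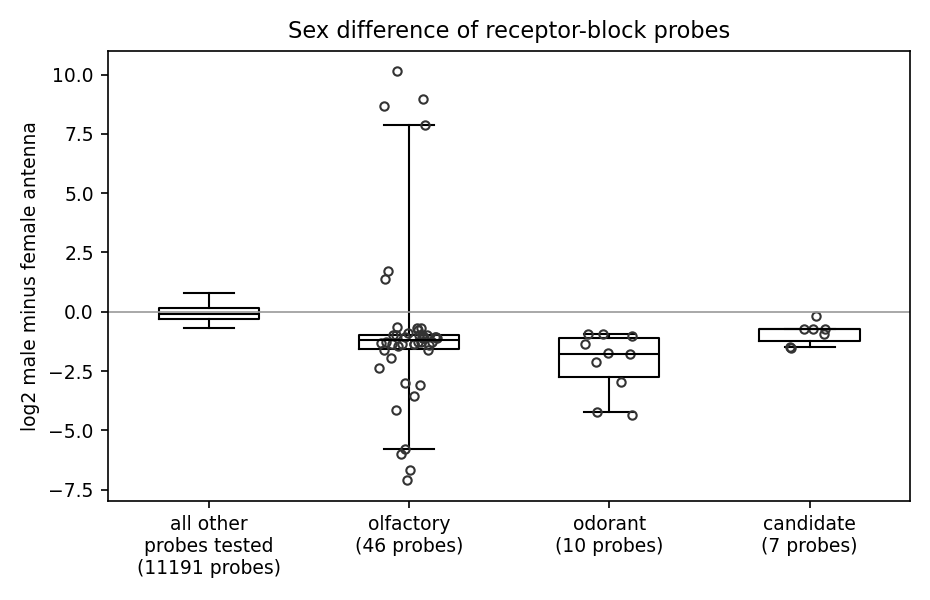
Log2 difference, male minus female antenna, of all other probes tested and of the tested olfactory, odorant and candidate probes of the receptor block, with boxes from the lower to the upper quartile, a line at the median, whiskers at the percentiles 5 and 95, and 1 point per receptor-block probe. The medians of the named words were -1.19, -1.78 and -0.73, all below 0.

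Over the whole array, 218 probes (181 clusters) were higher in male and 166 (154 clusters) in female antenna, of 11256 probes tested with limma, and 2188 had an unadjusted p below the threshold. A difference of at least 2-fold was found for 174 and 104 of them. Of the 384 probes that passed, 279 were detected on all 8 arrays, with a median difference of 2.34-fold, and 8 higher in male and 16 higher in female antenna were undetected on every array of the other sex. Of the probes without a describing name, CUST_3448_PI424196092 (GenBank AI172711.1) was higher in male antenna by 5.03 ± 0.33 on the log2 scale (limma, adjusted p = 0.000388), as was CUST_3457_PI424196092 (AI172701.1), by 4.30 ± 0.38 (adjusted p = 0.00113). The latter belongs to a cluster of 18 overlapping probes. CUST_5214_PI424201821 and CUST_7565_PI424201821, from assembly contigs, were lower in male antenna, with log2 differences of -2.59 ± 0.29 and -2.52 ± 0.30 (adjusted p = 0.00300 and 0.00373).

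Of the 13 groups of sequences formed from names, 9 passed the competitive test between the sexes with the preset correlation and 0 with an estimated one. The correlation was estimated without slide in the fit, so differences between the slides enter it, and an estimate with slide in the fit was not made. Olfactory targets were lower in male antenna as a group, with 16 of 27 (26 different) lower and 2 higher at the probe level (median -1.27, adjusted p = 2.63e-14, and adjusted p = 0.0645 with an estimated correlation). Odorant targets were also lower, 5 of 6 at the probe level (median -1.93, or -1.72 with limits, adjusted p = 1.78e-07, and 0.0645 as adjusted p with an estimated correlation). Candidate targets were lower with 1 of 5 past the threshold (adjusted p = 0.0218, and adjusted p = 0.242 with an estimated correlation). GenBank sequences with the letters AI were higher in male antenna, with 39 of 242 higher and 2 lower (adjusted p = 2.72e-13, and adjusted p = 0.104 with an estimated correlation), where the 39 stand for 18 clusters. Those with the letters EH were lower, with a median of -0.29, although 1 of 153 was lower and 0 were higher at the probe level (adjusted p = 6.78e-06, and adjusted p = 0.167 with an estimated correlation). For the letters BE the test gave higher values in the male with a mean of 0.34 and a median of -0.03, which differ in sign (adjusted p = 0.00126, and adjusted p = 0.479 with an estimated correlation). The remaining 3 that passed, BF, BM and other GenBank sequences, had medians of 0.03, 0.13 and 0.18 (adjusted p = 0.0218, 0.0218 and 0.000102, and adjusted p between 0.167 and 0.408 with an estimated correlation). BG, BI, CA and PROT_fasC sequences did not pass, and the median and mean of BG, CA and PROT_fasC sequences differed in sign.

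With slide as a block, 651 probes were higher in male and 1192 in female antenna, 4 and 53 of them in the receptor block, and all 384 probes above were among them. Within slide 1 alone the counts were 57 and 33, and within slide 2 alone 137 and 118. The 37 receptor-block probes higher in female antenna fell to 11 within slide 1, 21 within slide 2, 12 with spike-in scaling and 14 without the filter on dim probes. The 65 block probes had medians of -1.21 on slide 1 and -1.18 on slide 2, and those tested within slide 1 alone one of -1.25. The receptor-block median lay between -1.15 and -0.84 under every scaling that was run. Sex and place on the slide coincided on both slides and could not be separated. The counts of 218 and 166 fell to 138 and 102 without male pool 1, to 140 and 97 without male pool 4, to 102 and 62 without female pool 3, and to 101 and 65 without female pool 4.

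The second comparison set the antenna, as the mean of the sexes, against larval midgut. Every tested receptor-block probe, 65 of 65, was higher in antenna, and 62 of them were well above background on no midgut array. No block probe was well above background on all midgut arrays, so all 65 entered the test through detection in antenna. That filter largely set their direction in advance. Without it, 129 of the 130 block probes were called higher in antenna, among them probes detected on no array, so the count itself says little. The 34 probes of the block detected on all 8 antennal and no midgut arrays were higher in antenna by a median of at least 49-fold, from at least 17.1-fold to at least 382-fold. These limits hold for the background-subtracted signal: the fitted log2 median of the 65 probes, 6.83, was 2.72 with normexp background, 4.82 with quantile normalization and 5.09 with scaling to the array median. In contrast, 161 of 185 tested PROT_fasC targets were higher in midgut. In the sex comparison, where detection in antenna was needed, 40 PROT_fasC targets were tested. Most of the 185 thus entered through detection in midgut, and the filter largely set their direction too.

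By name, 25 olfactory probes were detected on all antennal and no midgut arrays, with a median of at least 49.4-fold, from 17.1 to 156. The 6 such odorant probes had a median of at least 41.9-fold and the 2 such candidate probes one of at least 102-fold. The 5 targets given by the second part of the rule, in which candidate did not count as a describing name, were all named olfactory. CUST_5_PI424196207 (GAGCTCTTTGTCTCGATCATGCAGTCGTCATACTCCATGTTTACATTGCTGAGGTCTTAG) had a signal of -1.35 ± 0.73 in antenna (SD, n = 8) and was at least 125-fold higher there (limma, adjusted p = 2.20e-12). CUST_65_PI424196207 was at least 102-fold higher, CUST_42_PI424196207 at least 71.6-fold, CUST_92_PI424196207 at least 71.3-fold and CUST_71_PI424196207 at least 70.2-fold (limma, largest adjusted p = 5.55e-10). With normexp background their log2 differences were lower, at 4.31, 3.73, 3.63, 3.35 and 3.00 in the same order, all still past the threshold. The candidate probe CUST_100_PI424196207, outside the rule and chosen after its values were seen, had a signal above those of these last 4 and was at least 108-fold higher in antenna (limma, adjusted p = 2.73e-10). The chemosensory probe CUST_8_PI424196207, chosen after its value was seen, was at least 382-fold higher, although its partner CUST_7_PI424196207 was well above background on 2 of 4 midgut arrays. No named gene was higher in midgut, and none was detected on all midgut arrays, so the filter left little room for that direction.

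Over the whole array, 6874 probes (6422 clusters) were higher in antenna and 6077 (5198 clusters) in midgut, of 17021 probes tested with limma. Of these, 5145 and 6077 were detected on all arrays of the higher group, and 797 and 2259 were undetected on every array of the lower. A difference of at least 2-fold was found for 5830 and 5126. Of the probes that passed, 6593 were detected on all 12 arrays, with a median difference of 3.10-fold. CUST_3505_PI424196092 (GenBank AI172649.1) was higher in antenna by 11.98 ± 0.35 on the log2 scale, as was CUST_3334_PI424196092 (AI187521.1), by 11.36 ± 0.36. CUST_1892_PI424201821, from an assembly contig, and CUST_1941_PI424196092 (CA798674.1) were higher in midgut, with log2 differences between antenna and midgut of -9.07 ± 0.30 and -7.05 ± 0.29. All 4 were detected on all 12 arrays (limma, largest adjusted p = 1.95e-10).

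Of the 13 groups, 8 passed the competitive test between tissues with the preset correlation and 0 with an estimated one. All 27 olfactory targets (26 different) were higher in antenna (median 7.14, or 5.50 with limits, adjusted p = 3.51e-13, and adjusted p = 0.148 with an estimated correlation), as were all 6 odorant targets (median with limits 4.47, adjusted p = 0.000607) and all 5 candidate targets (median with limits 4.22, adjusted p = 0.00632), both with adjusted p = 0.148 with an estimated correlation. PROT_fasC targets were lower in antenna, with 161 of 185 lower (148 clusters), 16 higher and 8 neither (median -8.85, or -7.32 with limits, adjusted p = 3.89e-24, and adjusted p = 0.148 with an estimated correlation). GenBank AI sequences were higher in antenna, with 179 of 278 higher and 52 lower, or 129 and 50 clusters (median 4.22, or 4.05 with limits, adjusted p = 1.68e-09, and adjusted p = 0.0869 with an estimated correlation). BE sequences were higher with 166 of 255 higher and 59 lower, or 93 and 56 clusters (median 4.93, or 4.78 with limits, adjusted p = 1.12e-08, and adjusted p = 0.172 with an estimated correlation). EH sequences were higher with 166 of 227 higher and 18 lower, or 151 and 13 clusters (median 2.52, adjusted p = 8.72e-13, and adjusted p = 0.148 with an estimated correlation). Other GenBank sequences were higher with 131 of 238 higher and 80 lower, or 118 and 76 clusters (median 1.42, adjusted p = 0.0153, and adjusted p = 0.337 with an estimated correlation). BF, BG, BI, BM and CA sequences did not pass, and BM sequences had a median of -0.16 and a mean of 1.48, which differ in sign. The array was designed from antennal and gut sequences, so groups of sequences by origin are not independent evidence of where they are expressed. The olfactory, odorant and candidate groups held only targets that had entered the test through detection in antenna. Most PROT_fasC targets had entered it through detection in midgut.

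**Figure D3:**
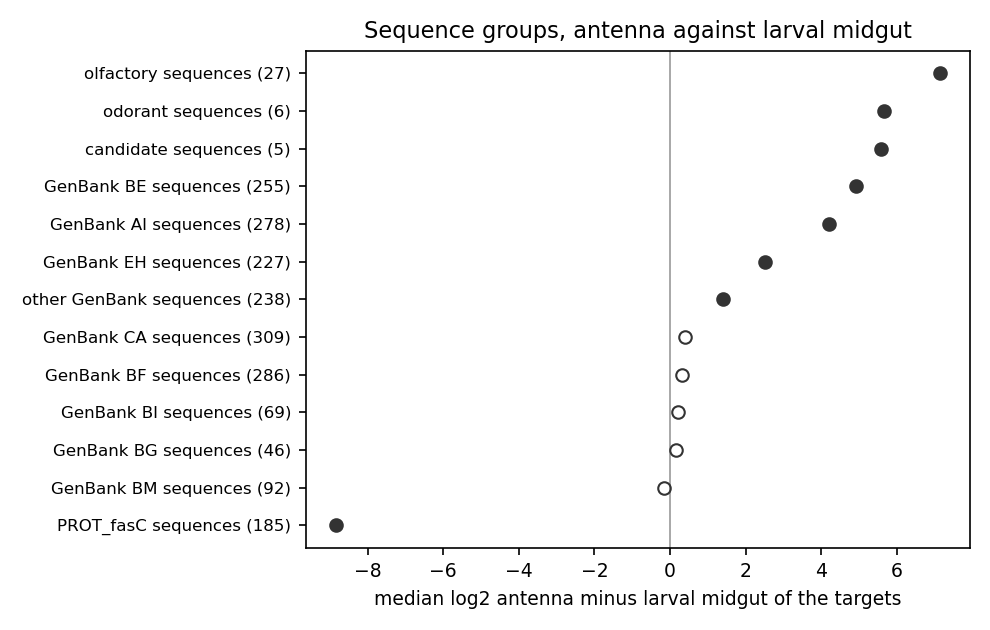
Median log2 difference, antenna minus larval midgut, of the targets in each of the 13 groups of sequences, with the number of targets tested in brackets, filled points for groups past an adjusted p of 0.05 with the preset correlation, and open points for the others. Olfactory sequences had the highest median, 7.14, and PROT_fasC sequences the lowest, -8.85, both as fitted values that include undetected groups.

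Slide, developmental stage and tissue coincided in this comparison and could not be separated. The balance of the counts moved with the scaling, with 3176 higher in antenna and 11341 in midgut when arrays were scaled to their medians, and 7561 and 2907 when scaled to bright spike-in probes, which shifted the median of all probes by -1.74 and 0.82. The shift was -0.42 with the 75th percentile over all probes, -0.17 with quantile normalization and 0.13 with normexp background, and under each of these scalings at least 64 of the 65 receptor-block probes stayed higher in antenna. Of the probes higher in male antenna, 156 were also higher in antenna than midgut and 40 were higher in midgut. Of those higher in female antenna, 109 were higher in antenna and 33 in midgut. All 11256 probes tested between the sexes had been detected in antenna, and their share higher in antenna was not computed. These counts therefore do not show whether the overlap is particular to probes that differ between the sexes.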

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

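The tests on male pool 3 were chosen only after the result was seen, and all tests of the receptor block and of the sequence groups rest on names that were read from the array after the data were examined. The other tests were chosen before their results were seen.

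Receptor-block probes had lower signals in male than in female antenna, with a median log2 difference of -1.11 (95% bootstrap interval -1.36 to -0.99, 65 probes). Intervals in this paragraph come from resampling probes measured on the same arrays. They treat probes as independent, although many of the 65 are partners of the same target, and carry no spread between pools. A shift of all probes of the same brightness was argued against by 1150 other probes matched on signal, whose median was -0.10 (-0.12 to -0.08). Each antennal slide held pools of both sexes in equal number, so an even difference between slides cancels by design. The pattern was seen on both, with medians of -1.21 on slide 1 and -1.18 on slide 2. The place of an array on its slide was tested on the midgut slide, where matched probes differed between places 1 and 2 and places 3 and 4 by a median of -0.13 (916 probes), which argues against a place effect of that size on that slide. On the antennal slides sex and place coincide, so an effect of place particular to those slides was not tested. A difference between the sexes in how strongly these targets are expressed, or in how many antennal cells express them, may account for the pattern and stays open as an untested hypothesis.

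An olfactory target outside the rule for named genes, chosen after its values were seen, was bright in all 4 female pools and well above background in male pool 3 alone among the male pools. In that pool CUST_49_PI424196207 reached 22.4% and CUST_50_PI424196207 15.3% of the female level, while the other 3 male arrays held background values, so the difference between the sexes is not measured. A flaw of single spots was argued against, since the second probe, which does not overlap the first, lay 4.93 log2 units above the highest of the other male pools, themselves background values, and at least 15.4-fold above the mean of their limits. RNA of female antennae in male pool 3 could not be decided: CUST_104_PI424196207, left out of the comparison because it was also detected in male pool 2, reached 21.8% in male pool 3, which goes with that explanation, but of 15 other female-biased probes those of 1 target lay below 15.3%, at most 8.00% for CUST_2_PI424196207 and 9.32% for CUST_1_PI424196207. Although not well above background, the signals of CUST_2_PI424196207 and CUST_1_PI424196207 were highest in male pool 3 among the male pools, at -4.44 and -5.01. The next highest were -6.89 and -6.41, so these 2 probes do not speak clearly against that explanation. The rest of the 15, among them the overlapping partner CUST_103_PI424196207 at up to 18.0%, were too close to the background. The need for 2 targets was set after the result was seen. Expression of the target in some males of that pool stays open and was not tested.

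Receptor-block probes were higher in antenna than larval midgut by a fitted median of 6.83 on the log2 scale, or 5.36 with every signal at or above the lowest detected signal of its array. Probes detected on no array, 13561 in all, differed by a median of 2.94 (95% of them between 1.78 and 3.95). They were chosen for lack of detection, and the block probes for detection in antenna, so a gap between them was built in. It cannot decide how far a higher background on the antennal arrays accounts for the difference. With normexp background the medians were 2.72 and 0.44, a gap of 2.27, so the size of the difference depended on the background method while all 65 probes stayed higher. Slide, stage and tissue coincide in this comparison, so a biological difference between tissues or stages stays open beside an effect of the slide or its background. None of them was tested apart.

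For the sexes, 2 of the 35 splits of the 8 antennal arrays gave as many probes higher on one side as the real count of 218, and 2 of 35 as many as 166, so chance was not excluded by these counts. The other split was that by slide, with 1991 probes in one direction and 1435 in the other, which points to a structure of the samples by slide. With slide as a block the counts were 651 and 1192, and none of the remaining 33 splits gave more than 6 in either direction. In the receptor block 1 of 35 splits, the real one, gave 4 probes higher in male antenna and 1 of 35 gave 37 higher in female antenna, with a highest other of 2 in each case. Many of these splits exchange arrays between slides, although 4511 of 11256 probes differed between slides. The share of 1 in 35 therefore does not exclude chance. The splits that keep 2 arrays of each side on each slide number 18, too few for a share under 0.05, and the other 17 gave 0 probes in either direction, over the whole array as in the receptor block. The 9 sequence groups were reached by 3 of 35 splits (highest other 9), so chance was not excluded. For the tissues, 1 of 100 splits gave 6874 probes higher in antenna (highest other 5554) and 1 of 100 gave 6077 higher in midgut (highest other 5822). Slide and tissue coincide and these splits exchange arrays between slides, so they do not exclude chance. The 8 sequence groups were reached by 8 of 100 splits (highest other 9), so chance was not excluded.

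In female antenna pool 2, CUST_1892_PI424201821 had a normalised log2 signal of -3.496, far below the other 3 female pools, at -2.574 to -2.398. This was 1 of 61 groups of 4 arrays looked at, and chance sets apart about 1 in 20. Negative-control spots, which the comparisons do not use, had a median intensity of 98.88 on the antennal arrays (32.59 to 160.5), against 2.009 to 2.612 on the midgut arrays.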

How the results depend on the processing

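Alternatives for the receptor block, the sequence groups, spike-in scaling, the percentile over all probes, clusters and the filter on the higher group were chosen after the data were examined. The balance of the counts turned for the sexes with slide as a block, and for the tissues with scaling to the array median, with quantile normalization (6523 and 6546), with the 75th percentile over all probes (5765 and 7310) and when only probes detected on all arrays of the higher group were counted (5145 and 6077). Single probes had opposite calls between tissues with the array median (1412), quantile normalization (177) and the authors' table (182), and in 0 cases between the sexes. For the sexes, the counts of 218 and 166 moved to 50 and 23 without the filter on dim probes (receptor block 14 higher in female), to 651 and 1192 with slide as a block, to 57 and 33 within slide 1 (block 11), to 137 in male within slide 2 (block 21), and to 37 and 19 with spike-in scaling (block 12). The count higher in female moved to 103 among probes detected on all arrays compared (block 18), to 91 with all 12 arrays in one fit and to 104 with at least 2-fold. With detection required on all arrays, 0 block probes were higher in male, because that filter removes targets undetected in females, and with 1 probe per target the block counts were 2 and 22 by construction. Leaving out 1 array gave 101 to 201 higher in male, 62 to 125 higher in female and 5 to 10 sequence groups, with 5 groups without male pool 1 or female pool 4. Single slides and left-out arrays have fewer samples; the cause of the other changes was not tested. With an estimated correlation 0 sequence groups passed for the sexes and 0 for the tissues. For the tissues, scaling to the array median gave 3176 and 11341 with 13 groups, spike-in scaling gave 2907 higher in midgut, no filter gave 25274 higher in antenna, and detection on all arrays gave 4058 and 2692 with 1 group, fewer probes being tested. Probes above background on at least 1 array numbered 16222 in male and 17093 in female antenna, and those positive and significant on all 4 arrays 16850 and 17801. Of 702 values of named probes, 649 kept their direction and side of the threshold, 53 kept the direction only and 0 reversed. The tests of fixed gene lists and of Z-linked genes were not run, nor were sequence groups with slide as a random block. Signal over background limits every fold against an undetected group.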

Other observations

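The probes named here were chosen after their values were seen, and the test of slide 1 against slide 2 and the principal components were added after the data were examined, while leaving out arrays and the slide block were planned. Several receptor-block names had no detected signal. Both gustatory probes, both melatonin probes, both isoform probes and the chemosensory probes CUST_39_PI424196207 and CUST_40_PI424196207 were well above background on 0 of the 12 arrays. The other chemosensory target, with CUST_7_PI424196207 at 0.70 ± 0.11 in male and 0.41 ± 0.24 in female antenna (log2, SD, n = 4 each), was well above background on all antennal arrays. Gustatory receptors detect tastants. The target named reverse was detected in part, with CUST_44_PI424196207 well above background on 3 of 4 male and 2 of 4 female arrays. One probe of a candidate target, CUST_102_PI424196207, was well above background on 3 of 4 midgut arrays and 0 antennal arrays, whereas its partner CUST_101_PI424196207 was detected on all 8 antennal arrays and on 3 midgut arrays.

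Over the antennal arrays, the first principal component held 46.4% of the variance and separated the slides, and the second held 24.5% and separated the sexes. With sex in the fit, 4511 of the 11256 probes tested (40.1%) differed between slide 1 and slide 2 (limma). With 1 array left out, between 164 and 321 probes differed between the sexes, against 384 with all 8 arrays and 1843 with slide as a block. The lowest signal called well above background lay between 136 and 217 on slide 1, between 360 and 678 on slide 2 and between 5.77 and 8.94 on the midgut slide.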
